A study of Homo sapiens with 12 samples.

How the data were processed

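RNA of HepG2 cells, treated with toosendanin or labelled as control, was measured in 12 libraries: 3 m6A IP and 3 input libraries per condition, per the labels. Libraries were made with a stranded mRNA kit that tags each cDNA molecule with a unique molecular identifier, per the labels' protocols. HISAT2, StringTie and DESeq are named in the submitters' processing notes, without versions. The genome build, the annotation, the counting settings and the tool that called and tested m6A regions are not given in the sources used here, so no coordinates are printed. Nothing in the labels says whether the libraries of a group came from separate cultures, so the expression p-values measure only the spread between these libraries, which may be technical.

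The expression file is a table of the authors' own comparison. Per the file headers it holds the columns of a DESeq2 result: a mean normalized count, a log2 fold change with its standard error, a Wald statistic (a score equal to their ratio, deposited by the authors), and a p-value with its adjusted p. It lists 28265 genes, of which 9159 have a mean of 0, 19077 have a p-value and 16552 an adjusted p. The lowest mean normalized count with an adjusted p is 1.8, and the deposited adjusted p equals a Benjamini-Hochberg adjustment over the genes that have one. Which libraries entered the comparison is not given in the sources used here. Of the gene names, 27650 matched a symbol or synonym of the reference tables.

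The m6A file gives, per region and per the file headers, whole-number read counts summed by the authors over the libraries of a condition for IP and for input, a log2 fold change of the IP over input ratio, a p-value and an FDR. It lists 46178 regions under 12985 gene labels, with a median of 3 regions per gene, and 917 regions carry more than 1 gene. The standard error implied by the deposited p-value and log2 fold change was within 1% of the Poisson error of the 4 summed counts in 99.5% of 45802 regions. The deposited p-values thus hold counting error only, and intervals or errors printed for m6A do the same. The deposited log2 fold changes differ from those of the summed counts by an offset between -0.1 and -0.004.

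Calls were taken at an adjusted p or FDR under 0.05 as the authors deposited them. The design set before the data were examined foresaw edgeR on counts per library. The files used here hold none, so the deposited tests were used in its place and nothing was refitted. A positive fold change was read as higher after toosendanin: over 8800 genes in the upper 50% of means, the deposited expression log2 fold change and the log2 ratio of summed inputs had a Pearson r of 0.94 across genes.

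The lists of genes, 33 in number, were fixed before the data were examined. They were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, with a preset correlation of 0.01, on the deposited Wald statistic for expression and on the signed statistic of the region with the smallest p for m6A, with Benjamini-Hochberg adjustment over lists of at least 5 measured genes. The list of 13 mitochondrially encoded transcripts had 0 measured genes. Overlaps of m6A and expression calls were tested with Fisher's exact test over genes with both measures. The relation of both measures was set against 100 simulated data sets with Poisson counts and no change. Named genes were chosen by a rule set before the data were examined: the 10 largest increases and 10 largest decreases among called genes in the upper 50% of mean normalized count, up to 4 members per list with the smallest adjusted p, up to 3 m6A regions per list, 5 genes per joint combination and the m6A enzymes and readers. Other list members printed were chosen after their values were seen, and some genes that the rule takes are not reported here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

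The set test was tested on simulated data: with 19077 genes, 4 of 4 shifted lists were called in the right direction and 0 of 22 unshifted ones. The simulated genes were independent of each other, so false calls of lists with correlated genes were not tested. For the m6A test on 24680 regions with 200 changed, 6.6% of changes of 0.25, 47.1% of changes of 0.5 and 78.9% of changes of 1.0 on the log2 scale were recovered, and 8 unchanged regions were called. These counts held Poisson error only, which the test assumes, so the few false calls say nothing about spread between libraries. The shares recovered also depend on how many regions were changed. Alternatives tried were stricter thresholds, a 2-fold limit, genes in the upper 50% of means, a new adjustment over all p-values, other forms of the set test, and for m6A a centring, a scaling to total counts, a widened statistic, removal of the enrichment trend and restriction to enriched or single-gene regions.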

Results

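N6-methyladenosine (m6A), the most common internal mark of mRNA, and gene expression were measured in HepG2 cells, an established line from a human liver tumour, after treatment with toosendanin and in a control. Toosendanin is a triterpenoid from the bark and fruit of Melia toosendan and is known for liver toxicity. RNA pulled down with an antibody against m6A (IP) and the RNA before the pull-down (input) were sequenced, with 3 libraries of each kind per condition and 12 in all. The labels give neither dose nor time. The deposited m6A table held counts summed over the libraries of a condition. Over its regions these came to 42316089 for control IP, 34131862 for control input, 29094328 for toosendanin IP and 24253006 for toosendanin input. Depth per library and values per library were therefore not analysed here, and no spread between libraries could be computed from the counts. The series asks how toosendanin acts on liver tumour cells, and the design implies a comparison of expression, a comparison of m6A and a comparison of both measures gene by gene.

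Toosendanin lowered the transcripts of mitosis and DNA replication and raised those of lysosomes and autophagy. In the authors' deposited table, DLGAP5, a mitotic spindle protein, fell by 4.55 ± 0.23 on the log2 scale (± is the standard error here and below), CENPE, a kinetochore motor, fell by 4.28 ± 0.21, and NDC80, which ties kinetochores to microtubules, fell by 4.17 ± 0.26. The same authors' deposited table listed APOA4, a lipid-carrying apolipoprotein, 4.44 ± 0.06 higher, the secreted ligand WNT11 4.87 ± 0.33 higher and CYP17A1, a steroid hydroxylase, 4.12 ± 0.31 higher. SQSTM1, an autophagy receptor, rose by 1.46 ± 0.05 and the lysosomal protease CTSB by 1.57 ± 0.06 in the authors' deposited table. By the adjusted p of the authors' deposited DESeq2 table, 5205 of 16552 genes with an adjusted p changed (31.4%), 2600 higher and 2605 lower after toosendanin. With a change of at least 2-fold, 1207 genes remained in that authors' deposited table, 635 higher and 572 lower.

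Among genes in the upper 50% of mean normalized count, the largest increases in the authors' deposited table also included CATSPERG, a subunit of a sperm calcium channel, at 6.25 ± 0.36, and BIRC7, an inhibitor of apoptosis, at 6.17 ± 0.91. ZNF114 at 3.38 ± 0.17, NDRG4 at 3.32 ± 0.20 and the axonemal dynein DNAH17 at 3.17 ± 0.12 followed in the authors' deposited table. U2AF1, a splicing factor, was listed at 5.04 ± 1.29 in the authors' deposited table, and is given as uncertain: a near-identical copy of the gene, U2AF1L5, is known, and how the counting treated it is not given in the sources used here. SNX22 was listed 3.36 ± 0.17 higher in the authors' deposited table. Its summed input counts of 57259 in control and 34325 after toosendanin gave a log2 change of -0.27 after centring over genes. SNX22 overlaps PPIB, listed there at a mean normalized count of 33020 against 475.4 for SNX22. The summed inputs of SNX22 may thus hold reads of PPIB, and they do not decide against the listed rise. The largest decrease among these genes in the authors' deposited table was that of IQGAP3, a scaffold protein, at -6.60 ± 0.85, while its summed input counts of 330 in control and 9 after toosendanin gave a log2 change of -4.65 after centring over genes. The spindle and kinesin genes ASPM at -3.96 ± 0.15, KIF4A at -3.90 ± 0.20, HMMR at -3.89 ± 0.21, CDC20 at -3.83 ± 0.22 and KIF2C at -3.82 ± 0.14 followed in the authors' deposited table. ID1, an inhibitor of differentiation and a target of BMP signalling, stood at -3.82 ± 0.26 in the authors' deposited table.

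**Figure D1:**
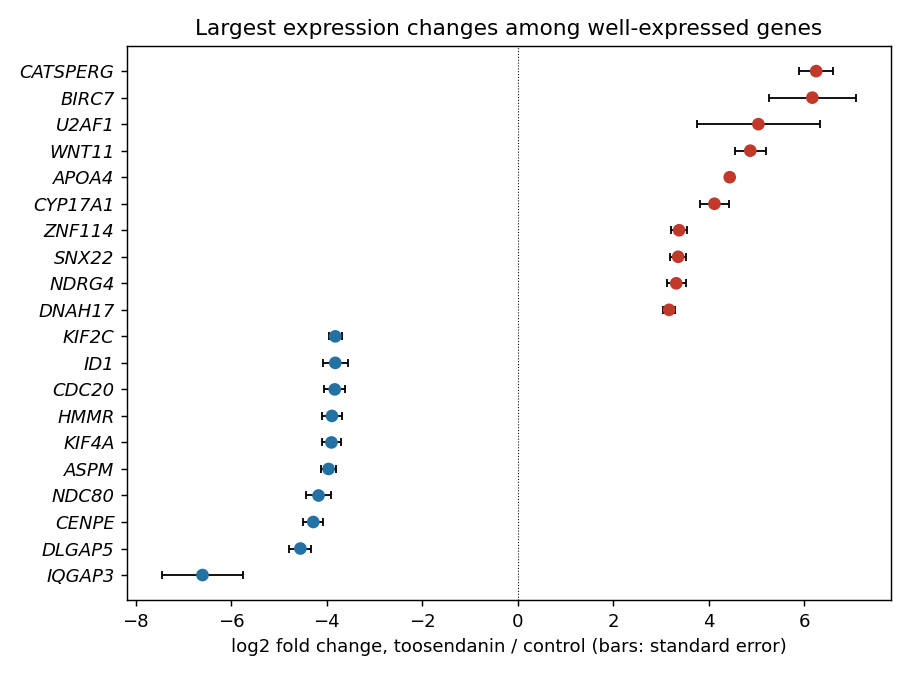
Log2 fold change of expression (x axis, toosendanin over control) for the 10 largest increases and 10 largest decreases among called genes in the upper 50% of mean normalized count, from the authors' deposited table. Points are the deposited values and bars their standard errors; IQGAP3 lies lowest at -6.60 and CATSPERG highest at 6.25.

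The cell cycle and mitosis list had the largest median change of the lists measured. In the authors' deposited table, 28 of its 30 measured genes fell and 0 rose (29 fell when adjusted over the list alone), with a median log2 fold change of -3.06. TOP2A, the topoisomerase that untangles chromosomes, stood at -3.76 ± 0.07 in the authors' deposited table, with CENPF at -3.64 ± 0.10, the mitotic kinase PLK1 at -3.32 ± 0.11 and TPX2 at -2.23 ± 0.08. Of 31 DNA replication genes 29 fell and 0 rose in the authors' deposited table (29 adjusted over the list alone), with a median of -1.10. RRM2, a subunit of ribonucleotide reductase, was listed at -3.04 ± 0.11 in the authors' deposited table, and the replicative helicase subunits MCM7 at -1.45 ± 0.07, MCM2 at -1.39 ± 0.09 and MCM3 at -1.11 ± 0.06. The set test cameraPR of limma, with Benjamini-Hochberg adjustment over lists, gave an adjusted p of 9.07e-125 for cell cycle and 3.22e-34 for DNA replication, both downward. Of 22 measured histone genes expressed in S phase, 3 fell and 0 rose in the authors' deposited table, and the list did not pass (cameraPR adjusted p = 0.371). Several of these genes were barely counted. H1-5 and H3C2, both among those that fell, had mean normalized counts of 4.225 and 4.181, and H3C1 and H2BC9 had 0.2739 and 0.8015. The result therefore does not show that these histone transcripts were spared.

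Autophagy and lysosome genes rose. In the authors' deposited table, 19 of 33 were higher and 1 lower (20 and 1 adjusted over the list alone), with a median of 0.45 and a cameraPR adjusted p of 1.69e-21. Ranked by log2 fold change the list did not pass (cameraPR adjusted p = 0.492), but it did in the rank version of that ranking (0.00256). MAP1LC3B, which coats autophagosomes, was 1.44 ± 0.08 higher and the sialidase NEU1 1.43 ± 0.07 higher in the authors' deposited table. Heat shock genes showed 11 higher and 1 lower of 22 in the authors' deposited table (12 and 2 adjusted over the list alone; cameraPR adjusted p = 0.000996, but 0.981 ranked by log2 fold change and 0.322 in the rank version of that ranking). Among them the small chaperone HSPB8 stood at 2.78 ± 0.34, HSPH1 at 0.48 ± 0.06 and HSPE1 at 0.46 ± 0.05 in the authors' deposited table, while HSP90AB1 stood at -0.27 ± 0.06.

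Parts of the translation machinery moved apart. Ribosomal protein genes were higher in 26 of 35 cases and lower in 0 in the authors' deposited table (28 higher adjusted over the list alone), by a median of 0.27, with RPL23 at 0.53 ± 0.05 and RPL6 at 0.35 ± 0.04. Ribosome biogenesis genes, which build ribosomes in the nucleolus, were lower in 21 of 30 cases and higher in 0 in the authors' deposited table (24 lower adjusted over the list alone), by a median of -0.40. Examples from the authors' deposited table are UTP20 at -0.79 ± 0.08, the pseudouridine synthase DKC1 at -0.68 ± 0.06 and NOP56 at -0.51 ± 0.05. The cameraPR adjusted p was 2.62e-09 for ribosomal proteins and 2.9e-10 for ribosome biogenesis. Ranked by log2 fold change neither list passed (cameraPR adjusted p = 0.876 and 0.462), but both did in the rank version of that ranking (0.0167 and 0.00164).

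Fatty acid synthesis genes moved upward under most forms of the set test, and other metabolic lists did so under fewer of them. Of 22 fatty acid synthesis and storage genes 14 rose and 1 fell in the authors' deposited table (14 and 1 adjusted over the list alone; median 0.50, cameraPR adjusted p = 2.37e-06, but 0.418 ranked by log2 fold change and 0.00541 in the rank version of that ranking), among them the lipid droplet gene CIDEC at 1.33 ± 0.16, ACSL1 at 0.92 ± 0.10 and SCD at 0.44 ± 0.06. Of 23 fatty acid oxidation and PPARA target genes 11 rose and 4 fell in the authors' deposited table (13 and 4 adjusted over the list alone; cameraPR adjusted p = 0.00471, but 0.956 ranked by log2 fold change and 0.347 in the rank version of that ranking). CPT1A, which brings fatty acids into mitochondria, stood at 1.30 ± 0.07 and HADHA, a subunit of the mitochondrial trifunctional protein, at 0.50 ± 0.05 in the authors' deposited table. Of 25 cholesterol genes 8 rose and 3 fell in the authors' deposited table (8 and 3 adjusted over the list alone; cameraPR adjusted p = 0.0216, but 0.0795 in the rank version and 0.0945 among the upper 50% of means), with the sterol synthesis enzymes MSMO1 at 0.57 ± 0.11 and EBP at 0.55 ± 0.07. Of 25 xenobiotic metabolism genes 9 rose and 4 fell in the authors' deposited table (10 and 4 adjusted over the list alone; cameraPR adjusted p = 0.0375, but 0.0918 in the rank version and 0.112 among the upper 50% of means). There the cytochrome CYP1A1 stood at 2.90 ± 0.20 and the sulfotransferase SULT2A1 at 1.78 ± 0.08 in the authors' deposited table, against UGT2B7 at -1.04 ± 0.14 and GSTA1 at -0.77 ± 0.10.

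Wnt target genes, cytoskeletal genes and cholangiocyte markers moved downward, and glycolytic genes did so less surely. Of 18 Wnt targets 9 fell and 3 rose in the authors' deposited table (10 and 3 adjusted over the list alone; median -0.50, cameraPR adjusted p = 1.91e-06, but 0.179 ranked by log2 fold change and 0.0156 in the rank version of that ranking), with the Wnt antagonists NKD1 at -1.74 ± 0.06, NOTUM at -1.15 ± 0.07 and DKK1 at -1.05 ± 0.16. Of 30 hypoxia and glycolysis genes 11 fell and 4 rose in the authors' deposited table (12 and 5 adjusted over the list alone; cameraPR adjusted p = 0.0107, but 0.0795 in the rank version, 0.792 ranked by log2 fold change and 0.347 in the rank version of that ranking). The glucose transporters SLC2A3 and SLC2A1 stood at -2.33 ± 0.20 and -1.88 ± 0.09 in the authors' deposited table, and ENO2 at 0.81 ± 0.10. Of 29 tubulin and cytoskeleton genes 17 fell and 5 rose in the authors' deposited table (20 and 6 adjusted over the list alone; cameraPR adjusted p = 1.07e-06, but 0.813 ranked by log2 fold change and 0.172 in the rank version of that ranking), with TAGLN at -2.09 ± 0.11, the alpha tubulin TUBA1B at -0.95 ± 0.07 and the actin crosslinker FLNA at -0.85 ± 0.07. Of 8 cholangiocyte markers 5 fell and 0 rose in the authors' deposited table (5 adjusted over the list alone; cameraPR adjusted p = 0.000327). SPP1 stood at -1.36 ± 0.07 and KRT19, which the cytoskeleton list also holds, at -0.55 ± 0.05 in the authors' deposited table.

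**Figure D2:**
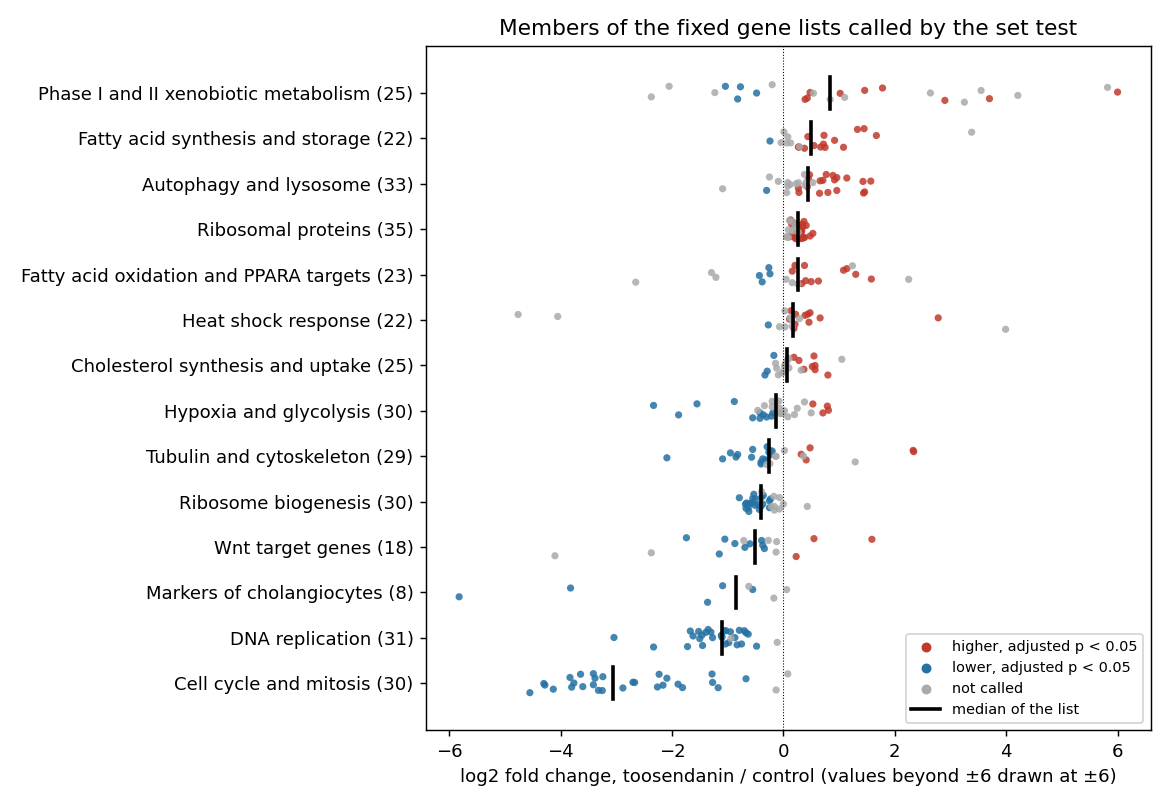
Log2 fold change of expression (x axis, toosendanin over control) of each measured member of the 14 fixed gene lists past the threshold of the set test, from the authors' deposited table. Points are genes, coloured by call; black bars are list medians, from -3.06 for cell cycle and mitosis to 0.84 for xenobiotic metabolism, and the number of measured genes follows each list's name.

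The remaining lists did not pass the set test. Their counts of changed genes are to be read against the 31.4% called among all genes with an adjusted p. Of 37 endoplasmic reticulum and integrated stress genes 12 rose and 9 fell in the authors' deposited table (cameraPR adjusted p = 0.127). The stress regulator NUPR1 stood at 2.93 ± 0.22, ATF3 at 1.41 ± 0.15 and the secreted factor GDF15 at 1.11 ± 0.09 in the authors' deposited table, but the cystine transporter SLC7A11 at -0.99 ± 0.11. Immediate early and MAPK genes split into 11 higher and 6 lower of 31 in the authors' deposited table (cameraPR adjusted p = 0.335), with EGR1 at 2.62 ± 0.13 and DUSP1 at 1.70 ± 0.12 against CCN2 at -2.66 ± 0.09 and DUSP6 at -1.37 ± 0.10. Of 27 p53 targets 4 rose and 8 fell in the authors' deposited table (cameraPR adjusted p = 0.176), including DDB2 at -1.25 ± 0.13. Of 31 apoptosis regulators 6 rose and 4 fell in the authors' deposited table (cameraPR adjusted p = 0.968), with the mitotic survivin gene BIRC5 at -2.50 ± 0.16. NRF2 and oxidative stress genes showed 10 higher and 4 lower of 27 in the authors' deposited table (cameraPR adjusted p = 0.0672), with the ferritin light chain FTL at 0.95 ± 0.08. Ferroptosis regulators showed 8 higher and 4 lower of 20 in the authors' deposited table (cameraPR adjusted p = 0.0639), with the transferrin receptor TFRC at 1.48 ± 0.07. Interferon genes showed 8 higher and 2 lower of 29 in the authors' deposited table (cameraPR adjusted p = 0.0639), with ISG15 at 1.21 ± 0.09, and nuclear oxidative phosphorylation genes 11 higher and 0 lower of 31 (cameraPR adjusted p = 0.0846).

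Liver function genes went both ways. Of 24 bile acid genes 6 rose and 4 fell in the authors' deposited table (cameraPR adjusted p = 0.488), with the conjugating enzyme BAAT at 1.67 ± 0.15 and the repressor NR0B2 at 1.48 ± 0.19 against the receptor FGFR4 at -0.64 ± 0.08. Secreted hepatocyte proteins split evenly into 10 higher and 10 lower of 30 in the authors' deposited table (cameraPR adjusted p = 0.968), with APOA2 at 0.96 ± 0.06 and the fibrinogen chain FGA at -0.78 ± 0.06. Of 27 acute phase and NF-kB response genes, called acute phase genes below, 8 rose and 6 fell in the authors' deposited table (cameraPR adjusted p = 0.968), with IL32 at 0.82 ± 0.07 and haptoglobin, HP, at -1.35 ± 0.07. Liver transcription factors split into 7 higher and 7 lower of 22 in the authors' deposited table (cameraPR adjusted p = 0.968), with CEBPA at 0.94 ± 0.18 and CEBPD at -1.08 ± 0.21. Genes of the epithelial-mesenchymal transition and the matrix showed 4 higher and 7 lower of 27 in the authors' deposited table (cameraPR adjusted p = 0.194). This list mixes epithelial and mesenchymal genes, with CDH1, the epithelial cadherin, at 1.32 ± 0.09 and LAMB1 at -1.03 ± 0.05. Its counts and p therefore do not measure a change of mesenchymal genes alone. Markers of fibroblasts showed 0 higher and 2 lower of 6, those of blood and immune cells 2 higher and 1 lower of 13, and those of endothelial cells 1 higher and 0 lower of 7 in the authors' deposited table. Their cameraPR adjusted p-values were 0.488, 0.335 and 0.873. Adjusted over the list alone, 1 more p53 target fell and 1 more ferroptosis and 1 more immediate early gene rose, and the counts of the other lists that did not pass were the same.

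Among m6A enzymes and readers, the catalytic writer METTL3 was lower by a small amount, at -0.36 ± 0.09 (adjusted p of the authors' deposited DESeq2 table = 0.000241). The eraser FTO stood at 0.18 ± 0.07 with an adjusted p of 0.0383 and the reader YTHDF1 at 0.30 ± 0.06 with 2.51e-05 in the authors' deposited DESeq2 table. METTL14 at -0.03 ± 0.11, WTAP at -0.07 ± 0.07, ALKBH5 at 0.10 ± 0.09, YTHDF2 at 0.03 ± 0.06 and YTHDF3 at 0.21 ± 0.27 did not pass in the authors' deposited table. The list of 25 measured writers, erasers and readers had 2 higher and 7 lower genes in the authors' deposited table (2 and 7 adjusted over the list alone; cameraPR adjusted p = 0.0733), with HNRNPC at -0.46 ± 0.05 and the writer subunit VIRMA at -0.41 ± 0.06.

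The expression calls rest on the authors' fit, and the set tests on a preset correlation of 0.01 between genes, because no values per library were used from which to estimate it. Ranked by log2 fold change in place of the test statistic, 4 lists passed, which were cell cycle, DNA replication, cholangiocyte markers and xenobiotic metabolism. The rank version of that ranking, added after the data were seen, passed 8: cell cycle, DNA replication, ribosome biogenesis, autophagy, fatty acid synthesis, cholangiocyte, Wnt and ribosomal protein genes, but not xenobiotic metabolism (cameraPR adjusted p = 0.0559). In the rank version on the test statistic, cholesterol (cameraPR adjusted p = 0.0795), xenobiotic (0.0918) and hypoxia genes (0.0795) did not pass. The test, the median and the mean of a list differed in sign for bile acid, secreted, acute phase, ferroptosis, liver transcription factor, fibroblast and endothelial genes. The direction of the deposited fold changes is not in the file header. It was settled from the log2 ratios of the summed input counts. These were first shifted by their median gap to the deposited fold changes. After that shift they had the same sign as the authors' deposited table in 4081 of 4134 called genes with enough counts (98.7%). The share thus speaks for the direction and not for the scaling, and the Pearson correlation given for the direction does not depend on the shift.

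For m6A, more regions lost signal than gained it in the authors' deposited table, a balance that turned over with the scaling, and most changes were small. Of 24688 regions with an FDR, 2209 passed the FDR of the authors' deposited table, 669 gained and 1540 lost, so that gains made up 30.3%. Of 49 regions in ribosomal protein transcripts 22 gained and 5 lost, with RPL15 at 0.46 ± 0.03 and RPL27 and RPS3 at 0.38 ± 0.02 and 0.38 ± 0.03, and the chaperone CALR lost, at -0.26 ± 0.01 in the authors' deposited table. Those RPL15, RPL27 and RPS3 regions had more input than IP reads, with a log2 IP over input ratio of -1.09, -0.64 and -1.28. Here ± is the counting error of the 4 summed counts, which leaves out the spread between libraries. The median size of the called changes was 0.32 on the log2 scale, and 4.5% reached a 2-fold change in the authors' deposited table. After the fold changes of all regions were centred on their median of -0.048, 1072 regions were gained and 863 lost, so that gains made up 55.4% of calls in place of 30.3%. With fold changes from the summed counts scaled to their totals over regions, whose median was 0.045, 1816 were gained and 566 lost (76.2% gained). The direction of the overall balance was thus not settled. The deposited p-values carry counting error only, and widening them by the spread of the statistic over regions, 1.51 times the counting error, left 435 calls with 145 gained and 290 lost.

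Gained and lost regions differed in how strongly the antibody enriched them. Regions were put into 10 groups of equal size by their IP over input ratio. In the group with the lowest ratio 181 were gained and 117 lost, and in the group with the highest ratio 2 were gained and 279 lost. The median log2 fold change of the authors' deposited table went from 0.031 in the former to -0.156 in the latter. Of the gained regions 77.9% had more input than IP reads in the unscaled counts, against 27.2% of the lost (Fisher's exact test, two-sided, odds ratio 9.42, p = 3.78e-111). Among all regions with an FDR the share was 42.8%. Regions are not independent replicates, so the p of that Fisher test does not measure the spread between libraries. Restricted to regions with more IP than input reads once each was scaled to its total count, and adjusted over these regions, 78 were gained and 979 lost. Scaled to total counts, the group with the highest ratio still held 13 gained and 100 lost.

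**Figure D3:**
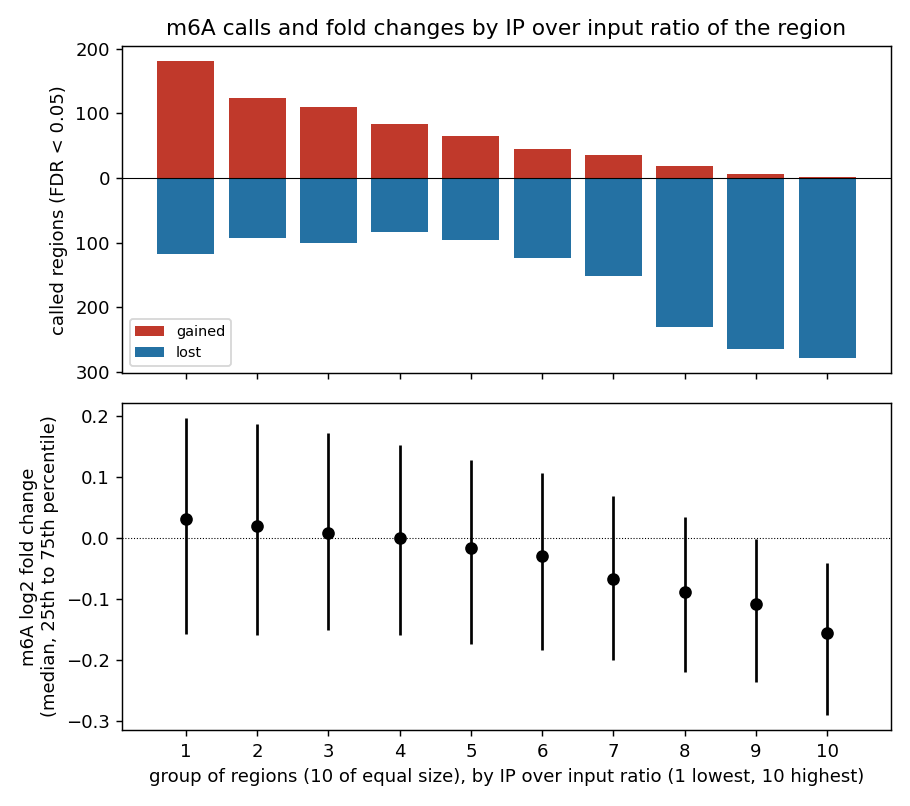
Upper panel, number of m6A regions gained (above 0) and lost (below 0) at the FDR of the authors' deposited table in each of 10 equal groups of regions by IP over input ratio. Lower panel, median m6A log2 fold change (points) with the 25th to 75th percentile (bars), from 0.031 in the lowest group to -0.156 in the highest.

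The largest gains in the authors' deposited table were in CPSF7, a cleavage and polyadenylation factor, at 1.52 ± 0.44, PPIP5K2 at 1.47 ± 0.34, the septin SEPTIN7 at 1.43 ± 0.25, CBWD1 at 1.33 ± 0.19 and the DNA primase subunit PRIM1 at 1.29 ± 0.34. PPIP5K1P1-CATSPER2 at 1.22 ± 0.21, CREM at 1.19 ± 0.39, TNRC6B at 1.19 ± 0.40, FAM126A at 1.18 ± 0.35 and KLF3 at 1.18 ± 0.36 followed in the authors' deposited table. SEPTIN7 and TNRC6B each also had a lost region. The largest losses were HSPA13 at -2.54 ± 0.84, RUFY3 at -2.28 ± 0.65, PLCB1 at -2.26 ± 0.71, ELF2 at -2.09 ± 0.54 and ARL6IP4 at -1.94 ± 0.63 in the authors' deposited table. TOMM70 at -1.85 ± 0.56, HSPA14 at -1.82 ± 0.62, TBC1D20 at -1.80 ± 0.48 and the mitochondrial calcium channel MCU at -1.80 ± 0.57 came next in the authors' deposited table. A region of TERF2, a telomere protein, had 33 IP counts in control and 0 after toosendanin over 19 input counts in each, and no fold is given for it. These regions rest on few counts, such as 24 and 8 IP counts for HSPA13. Among the gains, the regions of PPIP5K2, CBWD1, PRIM1, PPIP5K1P1-CATSPER2, CREM and KLF3 had more input than IP reads. The same held for TERF2, RUFY3, ELF2, TOMM70, TBC1D20 and MCU among the losses, and for none of the other regions named here. With the statistic widened by its spread over regions, SEPTIN7, CBWD1 and PPIP5K1P1-CATSPER2 still passed and the other named gains and losses did not.

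Of 49 regions in 32 ribosomal protein genes, 22 were gained and 5 lost in the authors' deposited table (20 genes gained and 3 lost by their region of smallest p, 23 and 3 adjusted over the list alone; cameraPR adjusted p = 5.79e-30). These regions had low enrichment, with a median log2 IP over input ratio of -0.56. Removing the trend with that ratio left 21 gained and 7 lost, but on the mean log2 fold change of each gene's regions the list did not pass (cameraPR adjusted p = 0.326), while the rank version on those means did (0.0153). Genes of the epithelial-mesenchymal transition and the matrix, called matrix genes below, had 11 regions gained and 3 lost of 63 in the authors' deposited table (5 genes gained and 1 lost, 7 and 1 adjusted over the list alone; cameraPR adjusted p = 0.00798), led by fibronectin, FN1, at 0.34 ± 0.02, which also had a lost region. That gained FN1 region had more input than IP reads, with a log2 ratio of -1.27. Endoplasmic reticulum stress genes had 2 gained and 9 lost of 89 in the authors' deposited table (1 gene gained and 7 lost, 4 and 11 adjusted over the list alone; cameraPR adjusted p = 0.0327), with PDIA4 at -0.20 ± 0.02 and HSPA5 at -0.13 ± 0.02. Scaling changed the counts of stress genes to 6 gained and 7 lost when centred, 4 and 6 with the trend removed and 11 and 4 scaled to total counts. The list did not pass in any of these (cameraPR adjusted p = 0.375, 0.256 and 0.997). Matrix genes passed in each, with 13 gained and 0 lost when centred, 12 and 2, and 21 and 0. Both lists lost their call in the rank version of the test (cameraPR adjusted p = 0.171) and on each gene's mean log2 fold change.

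Ribosome biogenesis genes had 3 regions gained and 12 lost of 85 in the authors' deposited table (2 genes gained and 11 lost, 5 and 11 adjusted over the list alone; cameraPR adjusted p = 0.05, just under the threshold before rounding), with the nucleolar protein NCL at -0.11 ± 0.01. The call was lost in the rank version (cameraPR adjusted p = 0.171) and on mean log2 fold changes, where the direction was upward (0.895). With the enrichment trend removed these became 7 gained and 2 lost, centred 4 and 4, and scaled to total counts 8 and 4, without a call in any (cameraPR adjusted p = 0.847, 0.528 and 0.942). With the trend removed, the best-covered region of NPM1 turned from -0.09 ± 0.01 in the authors' deposited table to 0.03. The other 23 tested lists had cameraPR adjusted p-values from 0.0709 to 0.984. Secreted hepatocyte proteins had 13 regions gained and 14 lost, cholesterol genes 6 and 11, acute phase genes 9 and 5, immediate early genes 0 and 8, and cell cycle genes 1 and 1 in the authors' deposited table. Centred, the counts were 21 and 11 for secreted proteins, 8 and 7 for cholesterol, 12 and 2 for acute phase and 0 and 6 for immediate early genes. Scaled to total counts they were 27 and 7, 12 and 5, 14 and 2, and 2 and 6. With the trend removed they were 17 and 13, 6 and 9, 5 and 4, and 0 and 6. Acute phase genes then passed upward in all of these (cameraPR adjusted p = 0.00605 centred, 0.000765 scaled to totals and 0.0131 with the trend removed), though not in the rank version on the deposited statistic (0.519). The rank versions of these settings did not pass either (cameraPR adjusted p = 0.298, 0.348 and 0.444). Scaled to totals, secreted, NRF2 and cytoskeletal genes passed upward too (cameraPR adjusted p = 0.000285, 0.00167 and 4.27e-05). In the rank version of that setting secreted genes did not pass (cameraPR adjusted p = 0.0681), while NRF2 and cytoskeletal genes did (0.00273 for each). Single regions of genes whose expression changed included MAP1LC3B at -1.07 ± 0.13, KLF6 at -1.11 ± 0.21, FASN at -1.03 ± 0.15 and CYP27A1, an enzyme of bile acid synthesis, at -1.29 ± 0.26 in the authors' deposited table. Each of these regions had more input than IP reads, with log2 IP over input ratios of -0.32, -0.37, -1.33 and -0.96. Among writers, erasers and readers 1 region was gained and 8 lost of 82, including ALKBH5 at -0.62 ± 0.16, YTHDF3 at -0.24 ± 0.07 and YTHDF1 at -0.20 ± 0.06 in the authors' deposited table, while no region of METTL3, METTL14, WTAP, FTO or YTHDF2 passed. These counts became 4 gained and 4 lost when centred, 1 and 3 with the trend removed and 7 and 4 scaled to total counts. No direction is given for this list.

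For both measures together, 872 of the 9301 genes tested for each were called in both. Which combination was largest depended on the scaling, as given below. On the deposited calls, lost m6A with lower expression took in 326 genes against 269.3 for independent calls (Fisher's exact test, two-sided, odds ratio 1.34, Benjamini-Hochberg adjusted p = 0.000156). It held CENPF, the Wnt antagonist NKD1, the histone chaperone NASP and MYBL2, whose m6A stood at -0.87 ± 0.27, -0.17 ± 0.06, -0.21 ± 0.03 and -0.61 ± 0.20 in the authors' deposited table. Lost m6A with higher expression took in 285 genes against 250.9 (odds ratio 1.21, Fisher's exact test, adjusted p = 0.0145), among them SQSTM1 at -0.73 ± 0.17 and CTSB at -0.20 ± 0.03 for m6A in the authors' deposited table. Both also had a gained region, that of CTSB at 0.30 ± 0.06 in the authors' deposited table. Gained m6A with higher expression took in 131 genes against 101.6 (odds ratio 1.42, Fisher's exact test, adjusted p = 0.0022), with SULT2A1 at 0.22 ± 0.06 and the calcium-binding S100A6 at 0.30 ± 0.05 for m6A in the authors' deposited table. Gained m6A with lower expression took in 130 genes against 109.1 (odds ratio 1.28, Fisher's exact test, adjusted p = 0.0223), with PEG10 at 0.31 ± 0.09 and the condensin subunit NCAPD2 at 0.51 ± 0.13 for m6A in the authors' deposited table. Of the regions whose m6A change is given in this paragraph, only those of CENPF, NKD1 and NASP had more IP than input reads.

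On the deposited calls all 4 combinations thus held more genes than independent calls would give, but not under each setting. The Fisher tests took no account of a gene's counts or number of regions. The excess alone therefore does not show a link between both changes. Among genes in the upper 50% of means, gained m6A with lower expression and lost m6A with higher expression did not pass (Fisher's exact test, adjusted p = 0.0679 for each). In regions with more IP than input reads, each scaled to its total count, gained m6A with lower expression took in 14 genes against 15.2 (Fisher's exact test, adjusted p = 0.883). Centred on the median, gained m6A with higher expression was the largest group, at 212 genes against 168.0, and lost m6A with lower expression held 189 against 152.6 (Fisher's exact test, adjusted p = 0.000387 and 0.00142), while the other combinations did not pass (0.0705 for each). Scaled to total counts the largest was gained m6A with lower expression, at 355 against 298.6 (Fisher's exact test, adjusted p = 0.000264), and lost m6A with higher expression did not pass (0.161). With the enrichment trend removed it was again gained m6A with lower expression, at 210 against 153.0 (Fisher's exact test, adjusted p = 6.2e-07), and lost m6A with lower expression did not pass (0.564). No combination passed under every setting. Across genes, which are not independent replicates, the m6A change of the region of smallest p and the expression change had a Spearman rho of -0.081 and a Pearson r of -0.06. No p is given, since input libraries also enter the m6A ratio and can make such a relation negative with no change. With expression taken from the summed inputs this arises by construction. From these counts the covariance was -0.0165, within the range of -0.0227 to -0.011 of 100 simulated data sets with no change, and rho was -0.148 against -0.161 to -0.117. With each gene's regions averaged, 410 genes were called in both and of the 4 combinations gained m6A with higher expression alone passed (72 genes against 46.4, Fisher's exact test, adjusted p = 0.000224).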

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

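The m6A alternatives that centre, widen, detrend, scale to total counts, restrict to enriched or single-gene regions or rank the mean over regions, the rank version of the ranking by log2 fold change, the list and joint tests under other scalings, and the count of genes with inputs in the same direction, were chosen after seeing the data. No paired analysis was possible because the files used here hold no values per library. For the same reason fits with edgeR or DESeq2, other size factors, low-count filters, pseudocounts, leaving out a replicate, other splits of the samples and an estimated correlation were not run. The count of expression calls stayed within 1.5 times under every setting but a 2-fold limit, which by construction left 1207 (635 higher, 572 lower). Of the m6A calls, an FDR under 0.01 left 1229 (371 gained, 858 lost) and a 2-fold limit 99 (23 and 76). The widened statistic left 435 (145 and 290), and widened and centred 367 (223 and 144). Fold changes from the summed counts scaled to their totals gave 1816 gained and 566 lost. Centring alone gave 1072 gained and 863 lost, and removing the enrichment trend gave 863 gained and 729 lost. Regions with more IP than input reads, each scaled to its total count, held 1057 calls (78 and 979). The cause of these shifts was not tested beyond the tests given under the other observations. Under trend removal the best-covered NPM1 region reversed to 0.03. Ranked by log2 fold change 4 expression lists passed, and 8 in its rank version. The rank version ended the calls of cholesterol, xenobiotic and hypoxia genes and added interferon, oxidative phosphorylation and m6A machinery genes, and the upper 50% of means ended those of cholesterol and xenobiotic genes. For m6A, the rank version kept 1 list, ribosomal proteins, the mean log2 fold change over regions 0, and its rank version 1, ribosomal proteins. Genes called in both measures came to 410 on averaged regions, 8 with a 2-fold limit and 454 in enriched regions. The cause was not tested. Small m6A changes can be missed: 6.6% of simulated changes of 0.25 log2 were recovered, with Poisson error only and 200 regions changed.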

Other observations

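All 5 gene groups in this and the next paragraph were drawn up after the expression values were seen, partly because genes such as ID1 and CCN2 stood out, so their p-values are not independent evidence. Further lysosomal genes, none of them in the fixed list, were higher in 18 of 23 cases and lower in 0 in the authors' deposited table (median 0.64, cameraPR adjusted p = 3.21e-22). RRAGD, a GTPase that places mTORC1 on lysosomes, stood at 2.53 ± 0.21, the ceramidase ASAH1 at 2.14 ± 0.07, FLCN at 1.39 ± 0.11 and the protease TPP1 at 1.36 ± 0.10 in the authors' deposited table. Epithelial genes, mostly of junctions but with the proteases PRSS8 and ST14, the splicing regulator ESRP2 and the cytoskeletal linker EPPK1 among them, rose in 9 of 18 cases and fell in 3 in the authors' deposited table (median 0.28, cameraPR adjusted p = 4.02e-05, but 0.0965 in the rank version and 0.525 ranked by log2 fold change), with PRSS8 at 2.15 ± 0.13 and the junction genes CLDN6 at 1.78 ± 0.17, CLDN3 at 1.53 ± 0.24 and CDH1 at 1.32 ± 0.09.

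Targets of YAP and TEAD, of which the fixed lists also hold CCN1, CCN2, TAGLN and TGFB2, were lower in 9 of 18 cases and higher in 2 in the authors' deposited table (median -0.52, cameraPR adjusted p = 4.29e-07), with CCN2 at -2.66 ± 0.09, TAGLN at -2.09 ± 0.11 and CRIM1 at -0.60 ± 0.07, while ANKRD1 stood at 0.46 ± 0.13. Targets of BMP and SMAD signalling fell in 3 of 8 cases and rose in 0 in the authors' deposited table (median -0.65, cameraPR adjusted p = 0.00365), with ID1 at -3.82 ± 0.26 and ID3 at -1.94 ± 0.26, while ID2 stood at 0.36 ± 0.18 and did not pass. Genes of gluconeogenesis and the urea cycle were higher in 5 of 15 cases and lower in 3 in the authors' deposited table (median 0.06, cameraPR adjusted p = 4.02e-05, but 0.165 in the rank version and 0.992 ranked by log2 fold change). PCK1 at 2.46 ± 0.15, G6PC at 2.22 ± 0.20 and ASS1 at 1.82 ± 0.06 led that group in the authors' deposited table.

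Of the tests that follow, those of lower IP enrichment, of the authors' offset, of the scaling to totals, of a general loss of m6A and of few counts were chosen only after the result was seen. The losses of m6A lay in regions of high IP over input ratio, with a Spearman rho of -0.279 across regions from the summed counts, against -0.017 to 0.00926 in 100 simulated data sets with no change. Because the relation of -0.279 was computed without the authors' offset per region, the offset cannot be its source. A lower enrichment in the toosendanin IP libraries may account for the trend, since it would pull the ratios of all enriched regions toward those of the rest. A general loss of m6A predicts the same difference of -0.19 between the groups of highest and lowest ratio (10 groups), and these explanations cannot be told apart because no spike-in counts were used here. In genes with both a gained and a lost region, 77 of 103 (74.8%) had the lower IP over input ratio in the gained regions.

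The excess of m6A losses over gains was 2.3 to 1 in the deposited calls. It was 2.0 with the widened statistic and 0.81 after centring, and neither test decides, since 1 constant divides gains and losses alike and centring on the median balances them by construction. The scaling between conditions that the authors chose may account for the excess: the median of the summed-count fold changes was -0.002 with no scaling and 0.045 scaled to total counts, where losses over gains came to 0.31. Those totals cover regions and not whole libraries and weigh abundant regions most, so which scaling is right stays open. No biological explanation of the excess was tested.

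For 45 of the called genes the deposited expression change and that of the summed inputs differed by more than 1 on the log2 scale, although in some, such as IQGAP3 and NOS3, both went the same way. Reads of an overlapping gene are a candidate explanation for part of these: 19 of 45 overlapped a gene of higher mean count, against 258 of 4026 others (Fisher's exact test, two-sided, odds ratio 10.7, p = 1.77e-11). Few counts are another, since 26 of 45 lay in the lower 50% of means, against 227 of 4026 (Fisher's exact test, odds ratio 22.9, p = 1.03e-20). Within the upper 50% of means the overlap was 4 of 19 against 216 of 3799 (Fisher's exact test, odds ratio 4.42, p = 0.021). SNX22 with PPIB and CDC25C with FAM53C are examples. For SNX22 the summed input count of 57259 in control far exceeds its mean normalized count of 475.4, so such reads would lie in the summed inputs. Which measure holds them in the other genes was not tested, and neither was any biological explanation.

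The covariance of -0.0165 between m6A and summed input changes lay within the simulated range with no change, as given for both measures together.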
